A study of Mus musculus with 622 samples.

How the data were processed

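Single mouse embryos were profiled by SMART-Seq RNA sequencing after injection of a synthetic microRNA, miR-200c-3p or miR-465c-3p, into the zygote, with GFP-injected embryos as controls. Per the labels' protocols, oocytes of FVB/NJ females were either activated without sperm to give parthenotes or fertilized in vitro. Collection followed activation or fertilization by 28 hours for late 2-cell embryos, by 46 hours for 4-cell embryos and by 70 hours for compacted morulae. The labels give the size of the low dose only, about 200 molecules; the amounts behind the mid and high doses, the miR-465c-3p dose at the 2-cell stage and the dose in fertilized embryos are not stated. The same labels describe about 8 embryos per group and stage in each of 3 experimental replicates (2 in 1 experiment), with all treatments run in parallel each day and eggs of about 5 females pooled. The day of each embryo is not labelled. Of the 622 samples, 525 are embryo libraries with counts, 93 are 2-cell parthenotes of the Ago-REMORA assay and 4 are sperm small RNA libraries. Groups, stages and replicate numbers were read from the sample titles. The sperm samples carry the source label of a 2-cell parthenote and were grouped by their titles and protocol.

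The deposited expected counts were made by the authors with RSEM on the mm10 genome, per the labels' protocols, and are not normalized. The submitters' processing notes also name R 4.5.1, DESeq2 1.48.2, cutadapt, FastQC, STAR and featureCounts, with no role given. Each count table holds 23845 gene symbols, of which 23573 were placed on mm10 with the annotation provided. Totals of expected counts per embryo ran from 404357 to 6774824 with a median of 3118638, so counting error is small for genes well above 10 CPM (counts scaled to the library total) and large below about 1 CPM. The libraries carry no molecular identifiers. Differences between embryos include biological and amplification noise that counting statistics do not cover.

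Ago-REMORA fuses AGO2, the protein that microRNAs guide to their targets, to an RNA editor, so that edits mark bound transcripts. The authors deposited 1 table each for 3' UTRs, coding sequences and introns, in a unit that the file headers call EPKM. The abbreviation is not spelled out in the headers or labels, so an EPKM value is read here only as a level of editing on the authors' own scale, with unknown depth. Between 67.4% and 83.9% of its values are 0, and 3 columns per table match no labelled sample and were not used here. The authors scaled the sperm microRNA values to RPM (reads scaled to the microRNA total), per the labels' protocols. Deposited values hold 1 added to every RPM. Each column's lowest value is 1, and the sum exceeds that of RPM values by the number of microRNAs listed (1978). That 1 was subtracted. Less 1, every value tested (up to 200 times the smallest) was a whole multiple of the RPM of 1 read (tolerance 0.02 reads). This puts the sperm samples at 3329806 to 4312954 microRNA reads.

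Differential expression was tested with edgeR 4.0.16 in R 4.3.3: rounded expected counts, TMM normalization, filterByExpr by group, a quasi-likelihood fit over all groups of 1 stage and experiment, and Benjamini-Hochberg adjustment over the genes tested, with adjusted p under 0.05 as the threshold. There were 15 comparisons of a dose with its control, 5 of a dose with the low dose, and 3 tests of a difference between effects (interactions): the high dose of miR-200c at morula minus 4-cell, and the fertilized minus the low-dose parthenote effect at 4-cell and at morula. Fitted log2 fold changes are given with their standard error (SE), and levels as mean CPM ± SD over embryos. The genes named were fixed by rule before the data were examined: up to 10 rises and 10 falls past the threshold with mean CPM of at least 10 and a count of at least 1 in at least 50% of the embryos of the group where the gene is higher, and up to 4 members past the threshold of a list; where fewer than 6 genes passed, all that passed and the 3 with the smallest p that did not; and Zeb1, Zeb2, Ago2 and Dicer1 wherever tested with miR-200c. Zeb2 passed the filter in no such comparison. For other contrasts the rule took 3 rises and 3 falls, for EPKM 5 of each, and for sperm the 5 most abundant microRNAs and every entry of the miR-200 and miR-465 families. Predicted and Rik genes and pseudogenes were passed over except where fewer than 6 genes passed. The smallest p were not always those named.

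Gene lists were also fixed beforehand: major zygotic genome activation (ZGA) and 2-cell genes, maternal oocyte transcripts, pluripotency and inner cell mass, trophectoderm, primitive endoderm, published miR-200 family targets, interferon and RNA sensing, p53 and apoptosis, unfolded protein and integrated stress response, cholesterol synthesis, microRNA pathway, chromatin regulators, cell cycle, paternally expressed imprinted genes, cytosolic ribosomal proteins and oxidative phosphorylation. Markers of cumulus and granulosa cells and of sperm and spermatids had fewer than 5 genes past the filter and were not tested. The 16 lists were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with prior count 2), adjusted over the lists of a comparison, and again, as an alternative set beforehand, with a correlation estimated from the data. A list score per embryo, the mean log2 CPM of the list minus that of all genes tested, was compared between groups by permuting embryos 100000 times (two-sided). This score was added after the data were seen.

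A seed site was a 3' UTR match to positions 2 to 8 of the microRNA, CAGTATT for miR-200c-3p and CCCTGAT for miR-465c-3p. Of the genes counted, 18806 had an annotated 3' UTR, of which 2322 and 1320 held such a site. The seed site score of an embryo was the mean difference from the control mean, in log2 CPM, of genes with a site minus that of genes without, compared between groups by permutation (100000, two-sided), with 15 tests adjusted together. EPKM tables were filtered to genes above 0 in at least 25% of the embryos of either group compared, log2-transformed after adding the 10th percentile of the non-zero values (0.302, 0.218 and 0.0356 for 3' UTR, coding sequence and intron) and tested with limma's moderated test with trend. Totals per embryo and the share of 3' UTR EPKM in genes with a seed site were compared by permutation (100000, two-sided). The 50 genes with the smallest p for each microRNA against AGO2 alone, with higher EPKM, formed a list that was tested in the injected embryos with camera. Fold changes of pairs of comparisons were correlated across genes and set against permuted groupings of the embryos. Genes are not independent replicates.

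Alternatives set beforehand were DESeq2 1.42.0, RLE normalization, no low count filter, the replicate number as a block, 2 surrogate variables (sva 3.50.0), gene tests and seed scores without shallow embryos (under 20% of the median total or 50% of the median genes detected), 8mer sites only, matching on 3' UTR length and expression, 100 shuffled 7mers, other pseudocounts, no EPKM filter, Fisher's exact test, division by region totals, the number of genes above 0 in place of the EPKM total, 200 in place of 50 edited genes, and each sperm sample left out. Alternatives added after the data were seen were bands of 8 consecutive embryo numbers as a factor (a stand-in for unlabelled days), leaving out single extreme embryos (for named genes past the threshold, or with at least 40% of a group's sum in 1 embryo, that with the highest value), gene list tests without shallow embryos, Y-linked counts as a covariate, genes tested at both stages, list scores, the site or list of the other microRNA, and lists of edited genes other than the 50 with an estimated correlation. Other splits of the same embryos (30 per count comparison, 100 per EPKM comparison, the real one included) gave the counts that random groupings produce. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

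The tests were checked on simulated counts drawn from the real embryos' means and library sizes. With changes of 2-fold, edgeR recovered 31.3% of 67 changed genes among 10538 for the mid dose of miR-200c at the 2-cell stage, 49.3% among 10144 for the high dose at 4-cell, 71.6% among 10470 for the high dose at morula and 14.9% among 8999 for miR-465c at the 2-cell stage. For 3' UTR EPKM, 25.8% of 66 genes changed 4-fold were recovered among 2890.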

Results

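The series asks how the amount of a sperm-borne microRNA delivered to the zygote relates to gene expression in the early mouse embryo. Zygotes were injected with a synthetic copy of miR-200c-3p or of miR-465c-3p, controls received GFP, and 525 single embryos were profiled by RNA sequencing, with expected counts per gene. In parthenotes (activated without sperm), the miR-200c experiment held 28 control, 26 low-dose and 23 mid-dose embryos at the 2-cell stage. At the 4-cell stage it held 24 control, 23 low-dose, 22 mid-dose and 24 high-dose embryos, and at the morula stage 20, 24, 19 and 19 of these groups. Fertilized embryos injected with miR-200c numbered 21 against 21 controls at 4-cell and 23 against 23 at morula. The miR-465c experiment in parthenotes held 22 control and 21 injected embryos at the 2-cell stage, 23 control, 24 low-dose and 16 high-dose embryos at 4-cell, and 22, 29 and 28 at morula. Another 93 2-cell parthenotes carried the Ago-REMORA editing assay: 15 with the editor alone, 23 with AGO2 fused to the editor, 27 with AGO2 and miR-200c and 28 with AGO2 and miR-465c. Small RNA of 4 sperm samples completed the series.

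Totals of expected counts per embryo ranged from 404357 to 6774824 (median 3118638), and 6872 to 13088 genes had a count of at least 1 (median 11099). The median total was 2547112 in miR-200c 2-cell parthenotes, 2880220 at 4-cell and 3371835 at morula. Medians were 3106001 and 2759905 in fertilized 4-cell embryos and morulae, and 3200738, 3436925 and 3542486 in the 3 stages of the miR-465c experiment. The depth behind the editing values is unknown.

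Sperm carried miR-200c-3p at 484 ± 226 RPM (SD, n = 4), rank 89 among the microRNAs listed, and miR-465c-3p at 534 ± 394 RPM, rank 85. These are levels of single listed entries, a limit for miR-465c-3p given below. By means of log2 RPM the order of the entries is the reverse (442 against 404 RPM). The miR-200 family members miR-141-3p (29308 ± 6513 RPM, rank 8), miR-429-3p (10685 ± 4533) and miR-200a-3p (4378 ± 1269) were more abundant than miR-200c-3p, and miR-200b-3p (183 ± 15.9) less so. The 5p arm of miR-200c averaged 0.826 ± 0.681 RPM, and miR-429-5p was listed at 0 in all 4 samples. The most abundant microRNAs were miR-10b-5p (177993 ± 31935 RPM), miR-10a-5p (161545 ± 35921), let-7f-5p (103215 ± 40225), let-7a-5p (45202 ± 11191) and miR-22-3p (41614 ± 21998).

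Sperm samples 1 and 2 were alike and apart from the others. Of the 243 microRNAs at 10 RPM or more in every sample, 2 were over 2-fold apart between samples 1 and 2, 50 between 3 and 4, and from 80 to 127 between any of samples 1 and 2 and any of 3 and 4. miR-465c-3p measured 893, 852, 139 and 251 RPM in samples 1 to 4, a 6.42-fold range. miR-200c-3p measured 755, 561, 228 and 393 RPM, a 3.31-fold range. The other arms of the cluster averaged 536 ± 399 (miR-465a-3p), 598 ± 369.5 (miR-465a-5p), 530.2 ± 382 (miR-465b-3p), 2634 ± 1206 (miR-465b-5p), 2804 ± 1926 (miR-465c-5p), 74.4 ± 58.0 (miR-465d-3p) and 231 ± 162 RPM (miR-465d-5p). The remaining arms of the miR-200 family averaged 28.0 ± 7.39 (miR-141-5p), 76.7 ± 35.9 (miR-200a-5p) and 9.15 ± 4.88 RPM (miR-200b-5p). Across these 243, which are not independent replicates, log2 levels of sample pairs correlated with r from 0.920 to 0.992. The samples form 1 group, so no test was made.

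**Figure D1:**
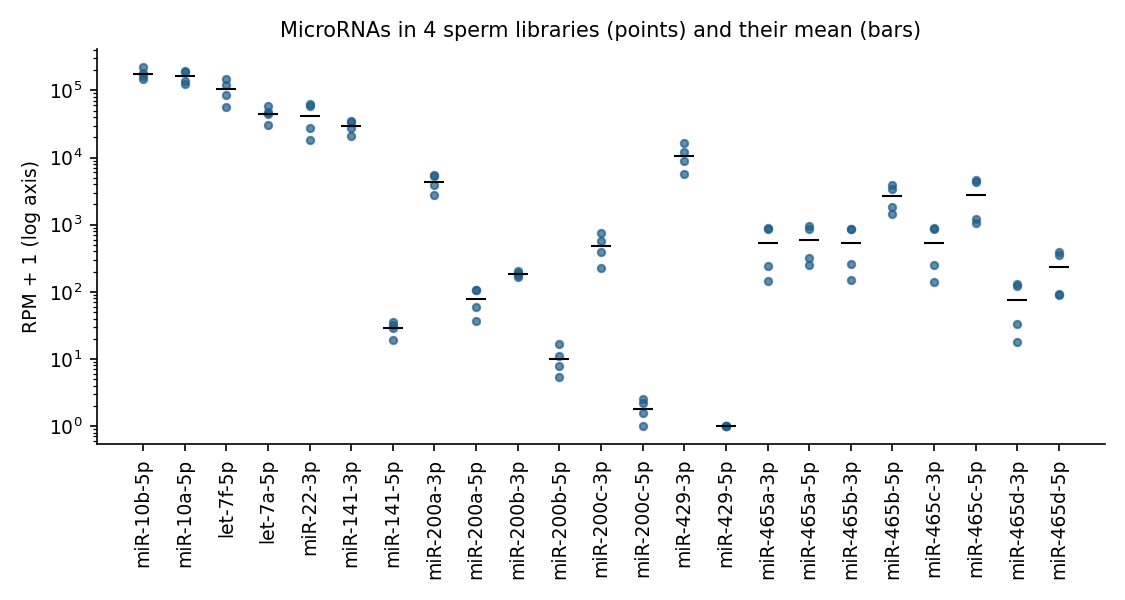
MicroRNA levels in sperm small RNA libraries, as RPM plus 1 on a log axis, with points for the 4 samples and bars for their mean. miR-200c-3p and miR-465c-3p, with means of 484 and 534 RPM, lie well below miR-10b-5p at 177993 RPM.

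At the 2-cell stage, when the zygotic genome is activated, the low dose of miR-200c left no gene past the threshold, and neither did the mid dose by edgeR. With bands of embryo numbers as a factor, added after the data were seen, edgeR called 239 at the mid dose. Mid-dose embryos held fewer transcripts of the cytosolic ribosomal proteins and more of the maternal transcripts stored in the oocyte, relative to all genes. Adjusted for the share of counts in the 10 most abundant genes, 22.9% of the ribosomal protein score difference (-0.17, SE 0.22) was left, and 18.3% of the maternal one (0.08, SE 0.11). That share itself differed by dose. All 84 ribosomal protein genes tested had a negative fold change at the mid dose, and 36 of 42 maternal transcripts a positive fold change. In 19 of 23 mid-dose embryos the ribosomal protein score lay below the control mean, and in 18 of 23 the maternal score lay above it. Among low-dose embryos 8 of 26 lay below the control mean for ribosomal proteins and 16 of 26 above it for maternal transcripts.

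The ribosomal protein score was 0.75 ± 1.02 against 1.52 ± 0.80 in controls (SD, n = 23 and 28, permutation adjusted p 0.0294), and the maternal score 3.90 ± 0.50 against 3.49 ± 0.45 (permutation adjusted p 0.0294). Camera, which compares the log2 fold changes of a list with those of all other genes, called ribosomal proteins lower (median -0.66, 84 genes, adjusted p 9.8e-29, estimated-correlation p 0.589) and maternal transcripts higher (median 0.31, 42 genes, adjusted p 1.13e-06, estimated-correlation p 0.589). Here and below the median is that of the list's log2 fold changes and both p values are adjusted. None of the camera calls of the 16 lists holds with an estimated correlation. Adjusted over the list alone, 61 ribosomal protein genes and 10 maternal transcripts passed, against 0 of either over all genes. Genes of zygotic genome activation (median -0.37, 35 genes, adjusted p 0.000364, estimated-correlation p 0.689) and of oxidative phosphorylation (median -0.22, 72 genes, adjusted p 0.00541, estimated-correlation p 0.689) were also lower by camera, with permutation adjusted p 0.197 and 0.142 for their scores. At the low dose camera called ribosomal proteins (median 0.04, 84 genes, adjusted p 0.0266, estimated-correlation p 0.967; median -0.06 with number bands) and oxidative phosphorylation (median 0.08, 72 genes, adjusted p 0.00697, estimated-correlation p 0.967) higher. The 10 most abundant genes took a larger share of counts at the mid dose, 9.65% ± 2.09 against 7.90% ± 1.37 (SD, n = 23 and 28, permutation adjusted p 0.013).

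**Figure D2:**
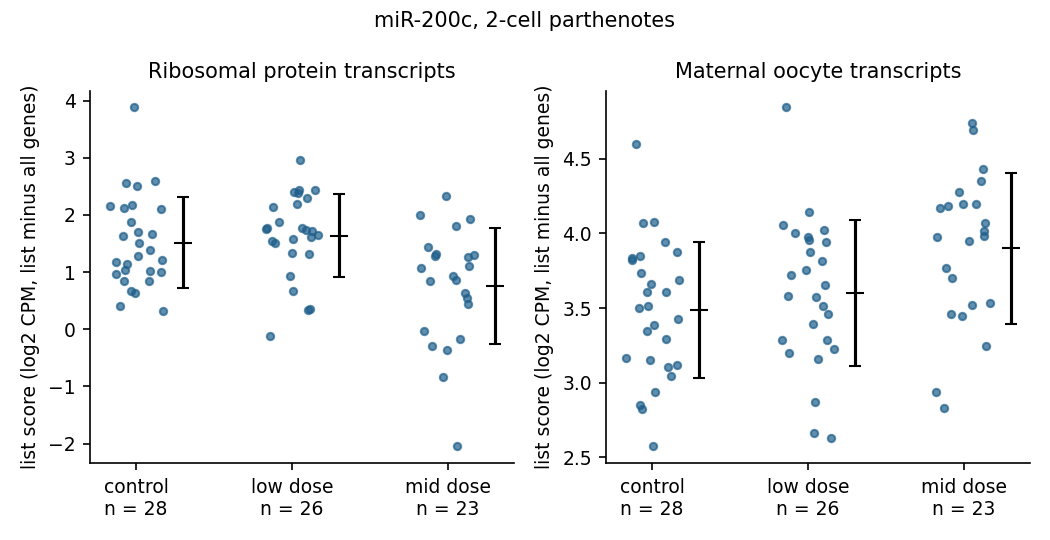
List scores of single 2-cell parthenotes (mean log2 CPM of the list minus that of all genes), with 1 point per embryo by miR-200c dose. The ribosomal protein score averages 0.75 at the mid dose against 1.52 in controls, and the maternal score 3.90 against 3.49.

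edgeR tested 11202 genes at this stage. It found 0 past the threshold at the low dose (136 at unadjusted p under 0.05, DESeq2 0) and 0 at the mid dose, where 1857 genes (16.58%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.0754. DESeq2 called 478 genes at the mid dose, 163 higher and 315 lower, all of them with edgeR p under 0.05 and the same direction. Without mid-dose replicate 26 it called 135 (44 higher, 91 lower), all just under the threshold. The smallest DESeq2 adjusted p there was 0.0485, over the 2978 genes that DESeq2 kept for adjustment. Among the 478 were 34 ribosomal protein genes, all lower, and 6 maternal transcripts higher and 1 lower. Taken from the DESeq2 calls after their values were seen, the oocyte linker histone H1foo (DESeq2 log2 fold change 1.02, adjusted p 0.0291) and Oas1d (0.96) were higher, and Rps29 (-1.07), the mitochondrial phosphate carrier Slc25a3 (-1.27) and the aspartate aminotransferase Got1 (-1.11) were lower. Genes with small edgeR p at the mid dose included the endosomal sorting gene Vta1 (log2 fold change 1.14, SE 0.26, adjusted p 0.142, chromosome 10, 14655333 to 14705489). Bpgm (0.86, SE 0.20, adjusted p 0.142) and Gtpbp1 (0.81, SE 0.19, adjusted p 0.147) followed. At the low dose Cst6, Wdr8 and Xkr8 had small p, at log2 -1.83 ± 0.61, -2.48 ± 0.83 and -2.54 ± 0.87 (SE).

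At the 4-cell stage, 2 genes fell at the mid dose of miR-200c. Socs3, an inhibitor of cytokine signalling through JAK and STAT (chromosome 11, 117966079 to 117969366), was at 330.4 ± 146 CPM (SD, n = 22) against 612 ± 302 CPM (n = 24) in controls (log2 fold change -0.89, SE 0.18, adjusted p 0.0324). The predicted gene Gm10697 (chromosome 3, 94071622 to 94072644) was at 62.0 ± 42.5 CPM (SD, n = 22) against 331 ± 546 CPM (n = 24) in controls (log2 fold change -2.42, SE 0.52, adjusted p 0.0489). Both calls were lost without the control embryo with the highest value, a choice that can only weaken a fall. For Socs3 that embryo, replicate 14 (1249 CPM), hardly exceeded the next control (1244 CPM). Without it Socs3 stayed at -0.82 with adjusted p 0.116, so its value does not rest on 1 embryo. For Gm10697 replicate 15 held 2622 CPM against 1004 CPM in the next control, and without it the gene gave -1.91 with adjusted p 0.235. The next genes were the chaperone cofactor Sgta (log2 fold change -0.43, SE 0.10, adjusted p 0.0757), Tex101 (log2 fold change -1.92, SE 0.46, adjusted p 0.157) and Opa3 (log2 fold change -0.74, SE 0.18, adjusted p 0.157). edgeR tested 10624 genes, with 655 at unadjusted p under 0.05 at the mid dose, and DESeq2 called 10, among them both edgeR genes.

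Camera called 2 lists at the mid dose, both lower: zygotic activation genes (median -0.14, 24 genes, adjusted p 0.00168, estimated-correlation p 0.370; 6 passed adjusted over the list alone) and ribosomal proteins (median -0.03, 85 genes, adjusted p 0.00722, estimated-correlation p 0.799). At the low dose edgeR found 0 genes (387 at unadjusted p under 0.05, DESeq2 0), and maternal transcripts were lower by camera, with 5 of 42 positive (median -0.43, 42 genes, adjusted p 2.77e-05, estimated-correlation p 0.936; permutation adjusted p 0.642). Genes of small p at the low dose included mitochondrial Opa3, the ubiquitin ligase Rnf4 and Mycbp, at log2 -0.70 ± 0.18, -0.31 ± 0.08 and 0.51 ± 0.15 (SE). At the high dose maternal transcripts were lower (median -0.27, 42 genes, adjusted p 0.00350, estimated-correlation p 0.584) and ribosomal proteins higher (median 0.14, 85 genes, adjusted p 2.55e-08, estimated-correlation p 0.584) by camera.

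At the high dose, 2 genes of the 2-cell-specific Zscan4 cluster passed the threshold in 4-cell parthenotes, through a single embryo. Zscan4d (chromosome 7, 11161643 to 11166148; log2 fold change 3.72, SE 0.75, adjusted p 0.0358) was at 98.5 ± 448 CPM (SD, n = 24) against 7.40 ± 7.56 CPM (n = 24) in controls, and Zscan4f (chromosome 7, 11397915 to 11402318; log2 fold change 4.19, SE 0.89, adjusted p 0.0437) at 195 ± 936 CPM (SD, n = 24) against 10.7 ± 20.5 CPM (n = 24) in controls. High-dose replicate 11 held 2202 CPM of Zscan4d, while the other 23 high-dose embryos averaged 6.99 ± 5.87 CPM with a highest value of 21.5. The same embryo held 4588 CPM of Zscan4f and 2364 CPM of Zscan4c, which did not pass (log2 fold change 3.78, SE 0.96, adjusted p 0.535). Without it the log2 fold changes were -0.07 (Zscan4d), -1.23 (Zscan4f) and -2.46 (Zscan4c), and 3 other genes passed, all lower and named after their values were seen: Gm21312 (-6.07), Gm8994 (-5.20) and Usp17lb (-5.34). The RNA sensor relative Ddx60 (log2 fold change -1.47, SE 0.40, adjusted p 0.638) and Cyp46a1 (log2 fold change -3.26, SE 0.90, adjusted p 0.638) followed. edgeR had 473 genes at unadjusted p under 0.05, and DESeq2, which replaces extreme counts, called 1 gene, Usp17lb (-5.22, adjusted p 0.0283), that edgeR did not.

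**Figure D3:**
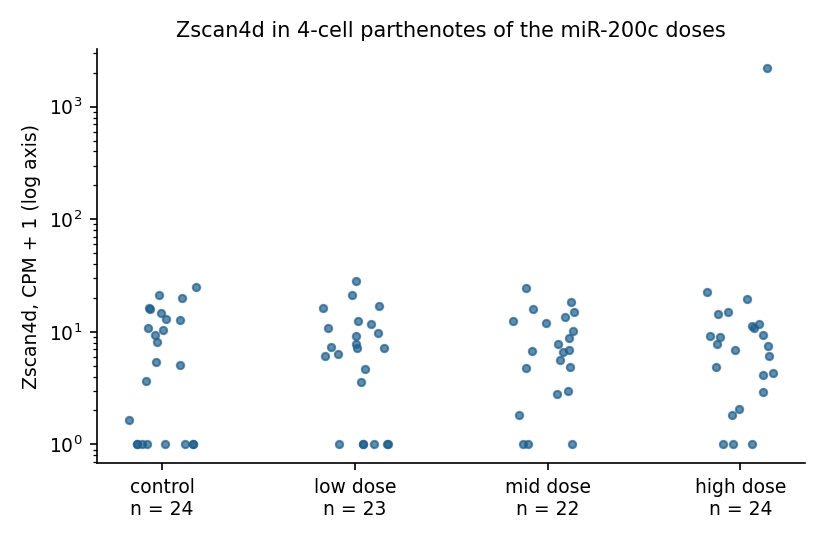
Zscan4d in single 4-cell parthenotes by miR-200c dose, as CPM plus 1 on a log axis, with 1 point per embryo. High-dose replicate 11 stands at 2202 CPM and the other high-dose embryos at or below 21.5 CPM.

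In morulae, where the outer cells take the first steps towards trophectoderm, edgeR called no gene at any dose of miR-200c. By camera, trophectoderm genes as a list were higher at all 3 doses, and primitive endoderm genes at the mid and high dose. Zygotic activation genes and ribosomal proteins were lower at all 3. The doses share controls, so their agreement is not replication. Published miR-200 targets, predicted to be repressed, were higher at the mid dose. None holds with an estimated correlation or by permutation of list scores.

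By camera trophectoderm genes were higher at the low (median 0.18, 25 genes, adjusted p 0.00841, estimated-correlation p 0.834), mid (median 0.10, 25 genes, adjusted p 0.000391, estimated-correlation p 0.445) and high dose (median 0.23, 25 genes, adjusted p 7.6e-05, estimated-correlation p 0.478), and primitive endoderm genes at the mid (median 0.42, 12 genes, adjusted p 0.0118, estimated-correlation p 0.445) and high dose (median 0.31, 12 genes, adjusted p 0.00751, estimated-correlation p 0.521). Zygotic activation genes were lower at the low (median -0.15, 13 genes, adjusted p 0.0466, estimated-correlation p 0.834), mid (median -0.25, 13 genes, adjusted p 0.0116, estimated-correlation p 0.445) and high dose (median -0.26, 13 genes, adjusted p 0.00279, estimated-correlation p 0.478). Ribosomal proteins were lower at the low (median -0.08, 85 genes, adjusted p 2.72e-11, estimated-correlation p 0.834), mid (median -0.17, 85 genes, adjusted p 3.03e-15, estimated-correlation p 0.445) and high dose (median -0.16, 85 genes, adjusted p 3.82e-13, estimated-correlation p 0.679). Of the published miR-200 targets 19 of 25 were positive at the mid dose (median 0.13, 25 genes, adjusted p 0.00411, estimated-correlation p 0.445). Oxidative phosphorylation was lower at the mid dose (median -0.11, 77 genes, adjusted p 0.000391, estimated-correlation p 0.888). At the low dose it was called higher (median 0.15, 77 genes, adjusted p 0.0397, estimated-correlation p 0.834), but its median turned to -0.01 with surrogate variables and -0.05 with number bands. The list scores gave permutation adjusted p of at least 0.137 in all of these. Adjusted over the list alone, 1 zygotic activation gene passed at the mid and 2 at the high dose, and no gene of the other lists called here.

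edgeR tested 10620 genes in morulae and called 0 at the low (578 at unadjusted p under 0.05, DESeq2 0), mid (522, DESeq2 1) and high dose (715, DESeq2 3). The smallest p at the low dose was that of the lipid carrier Apoe (chromosome 7, 19696244 to 19699188), at 148 ± 332 CPM (SD, n = 24) against 51.5 ± 21.1 CPM (n = 20) in controls (log2 fold change 1.52, SE 0.32, adjusted p 0.0638). Low-dose replicate 4 held 1683 CPM, the other 23 embryos 80.8 ± 58.3 CPM, and without it Apoe gave 0.64 (SE 0.21, adjusted p 0.760). Mep1b and Fbxl4 followed, with log2 fold changes of -1.30 ± 0.34 and 0.95 ± 0.25 (SE). At the mid dose Bex6 came first (log2 fold change -2.01, SE 0.44, adjusted p 0.174; DESeq2 adjusted p 0.00869), then Dtnbp1 and Mfsd1, at log2 -0.77 ± 0.22 and 0.50 ± 0.14 (SE). At the high dose the transcription factor Tfcp2 (log2 fold change -1.498, SE 0.33, adjusted p 0.201), Sh3bp5 (log2 fold change 1.70, SE 0.40, adjusted p 0.224) and the DNA repair glycosylase Mbd4 (log2 fold change -0.64, SE 0.15, adjusted p 0.224) had the smallest p. DESeq2 called Tfcp2 and Sh3bp5 (adjusted p 0.0213 each) and AF067063 (adjusted p 0.0487), a gene named after its value was seen.

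Zeb1, the best-known target of the miR-200 family, passed the threshold in no comparison where it was tested: its log2 fold change was 0.36 ± 0.66 (SE) and 0.74 ± 0.68 at the low and mid dose in 2-cell parthenotes, and -0.54 ± 0.87, -0.35 ± 0.88 and -0.80 ± 0.86 at the low, mid and high dose at 4-cell. Its level was low, 4.16 ± 4.19 CPM in 28 2-cell controls, and the 4-cell values rest on control replicate 1 (31.2 CPM), without which they were 0.17, 0.36 and -0.09. Ago2, the slicing Argonaute, ranged in log2 fold change from -0.37 (fertilized morulae) to 0.39 (high dose, morula, unadjusted p 0.0292) over the 10 miR-200c comparisons. Dicer1, the enzyme that cuts microRNA precursors, ranged from -0.61 (mid dose, morula, unadjusted p 0.00195) to 0.02 (fertilized morulae), with -0.46 ± 0.19 (SE, unadjusted p 0.0179) at the high dose in morulae. None of these passed the threshold, with adjusted p of at least 0.638 for Ago2 and Dicer1 and 0.607 for Zeb1.

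In fertilized embryos miR-200c left no gene past the threshold. At 4-cell the smallest p values were those of the non-coding RNAs Dancr (log2 fold change 0.89, SE 0.22, adjusted p 1.00) and Neat1 (log2 fold change 1.71, SE 0.45, adjusted p 1.00) and of the autophagy gene Wipi2 (log2 fold change -0.32, SE 0.09, adjusted p 1.00). In morulae they were the small heat shock protein Hspb1 (log2 fold change -2.58, SE 0.60, adjusted p 0.613), the Myc partner Max (log2 fold change 0.59, SE 0.14, adjusted p 0.615) and Utp14b (log2 fold change -0.79, SE 0.20, adjusted p 0.615). The Hspb1 value rests on control replicate 14 with 4463 CPM, against 44.9 ± 27.9 CPM in the other 22 controls, and was -0.21 (adjusted p 1.00) without it. Primitive endoderm genes were lower in fertilized morulae, 0 of 9 positive (median -0.41, 9 genes, adjusted p 0.000349, estimated-correlation p 0.186; permutation adjusted p 0.262), and no list was called at 4-cell. edgeR called 0 of 8940 genes at 4-cell (242 at unadjusted p under 0.05, DESeq2 0) and 0 of 9262 in morulae (348, DESeq2 0).

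miR-465c left no gene past the threshold by edgeR at any stage. High-dose morulae stood nearest to it. Genes of cholesterol synthesis and of trophectoderm were lower in these morulae as lists by camera. These calls are lost with an estimated correlation and by permutation. Among single genes, the nuclear receptor Nr5a2, a regulator of pluripotency genes, the ATP-gated channel P2rx7 and the cargo receptor Surf4 came closest.

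Nr5a2 (chromosome 1, 136843584 to 136960448) was at 57.2 ± 22.2 CPM (SD, n = 28) against 35.6 ± 8.21 CPM (n = 22) in controls (log2 fold change 0.68, SE 0.14, adjusted p 0.0569), P2rx7 (chromosome 5, 122643927 to 122692336) at 43.4 ± 61.7 CPM (SD, n = 28) against 5.40 ± 7.49 CPM (n = 22) in controls (log2 fold change 2.98, SE 0.64, adjusted p 0.0569), and Surf4 at 206 ± 57.7 CPM (SD, n = 28) against 287 ± 66.8 CPM (n = 22) in controls (log2 fold change -0.48, SE 0.11, adjusted p 0.0633). All 3 passed with RLE normalization (adjusted p 0.0439 each). By camera cholesterol synthesis genes were lower, 0 of 23 positive (median -0.27, 23 genes, adjusted p 7.42e-06, estimated-correlation p 0.539), trophectoderm genes lower (median -0.24, 25 genes, adjusted p 0.00260, estimated-correlation p 0.539) and ribosomal proteins higher (median 0.07, 85 genes, adjusted p 0.00317, estimated-correlation p 0.689), with permutation adjusted p 0.113, 0.113 and 0.483. With surrogate variables the first 2 medians turned to 0.03 and 0.07. edgeR tested 10498 genes and called 0 at the high dose (1124 at unadjusted p under 0.05, 10.71%), where DESeq2 called 27, and 0 at the low dose (580, DESeq2 0).

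In low-dose morulae p53 and apoptosis genes (median -0.16, 20 genes, adjusted p 0.0206, estimated-correlation p 0.587) and oxidative phosphorylation (median -0.12, 78 genes, adjusted p 0.000237, estimated-correlation p 0.665; median 0.04 with surrogate variables) were lower by camera. Small p values included those of Lrrc75a, the thiamine transporter Slc19a3 and Frmpd1, at log2 1.69 ± 0.41, 3.20 ± 0.82 and 1.10 ± 0.29 (SE). At 4-cell oxidative phosphorylation was higher at the low dose by camera (median 0.04, 79 genes, adjusted p 0.00913, estimated-correlation p 0.853; median -0.01 without shallow embryos). Small p values there included those of the adhesion receptor Selp, Apoa1bp and the actin bundler Fscn1, at log2 -4.92 ± 1.12, 1.04 ± 0.27 and -1.34 ± 0.38 (SE). Fscn1 was at -0.54 without control replicate 23 (6371 CPM). The high dose at 4-cell called no list. Small p values included those of Zfp707, Foxr1 and Ntmt1, at log2 1.21 ± 0.31, 0.96 ± 0.25 and 0.63 ± 0.18 (SE). In 2-cell parthenotes ribosomal proteins were higher by camera (median 0.23, 84 genes, adjusted p 0.00404, estimated-correlation p 0.744). Small p values there included those of the co-chaperone Dnaja3, the DNA damage kinase Atm and Rpp25, at log2 -0.72 ± 0.19, -1.20 ± 0.33 and -0.76 ± 0.24 (SE). edgeR called 0 of 9682 genes at 2-cell (94 at unadjusted p under 0.05, DESeq2 0) and 0 of 10023 at 4-cell, low dose (310, DESeq2 0) and high dose (313, DESeq2 0).

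Whether doses differ was tested directly against the low dose. In 2-cell parthenotes the mid dose of miR-200c held fewer transcripts of ribosomal proteins and of oxidative phosphorylation than the low dose. Ribosomal proteins, 1 of 84 positive, were lower by camera (median -0.72, 84 genes, adjusted p 2.13e-37, estimated-correlation p 0.150; permutation adjusted p 0.00624), as was oxidative phosphorylation (median -0.29, 72 genes, adjusted p 2.81e-06, estimated-correlation p 0.150; permutation adjusted p 0.00368). Adjusted over the list alone, 64 ribosomal protein and 2 oxidative phosphorylation genes passed. Zygotic activation genes were lower (median -0.40, 35 genes, adjusted p 5.39e-05, estimated-correlation p 0.554) and maternal transcripts higher (median 0.30, 42 genes, adjusted p 0.000263, estimated-correlation p 0.554; median -0.07 with surrogate variables) by camera, with permutation adjusted p 0.274 and 0.164. edgeR called 0 genes (1715 at unadjusted p under 0.05, smallest adjusted p 0.144), and DESeq2 345, or 112 without mid-dose replicate 26.

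Against the low dose at 4-cell, the high dose of miR-200c had 4 genes higher, all through high-dose replicate 11: Zscan4f (4.70 ± 0.93, SE), Zscan4d (3.77 ± 0.77), Gm2016 (4.96 ± 1.01) and BB287469 (4.69 ± 1.00), with adjusted p from 0.0148 to 0.0231. Without that embryo 0 genes passed, and the values were -0.69, -0.06, 0.23 and -0.53. With it, 260 genes had an unadjusted p under 0.05, and DESeq2 called 0. Ribosomal proteins were higher by camera (median 0.11, 85 genes, adjusted p 9.37e-05, estimated-correlation p 0.812). In morulae edgeR called 0 genes between high and low dose (793 at unadjusted p under 0.05, DESeq2 0), and oxidative phosphorylation was lower (median -0.23, 77 genes, adjusted p 0.000297, estimated-correlation p 0.823).

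For miR-465c the circadian repressor Bhlhe41 (chromosome 6, 145858243 to 145865420) was higher in high-dose than in low-dose morulae, at 11.9 ± 18.99 CPM (SD, n = 28) against 1.79 ± 1.81 CPM (n = 29) at the low dose (log2 fold change 2.71, SE 0.51, adjusted p 0.00786). Without high-dose replicate 7 (78.6 CPM) it gave 2.38 with adjusted p 0.0677. It was 1 of 695 genes at unadjusted p under 0.05, and DESeq2 called 3 genes, Bhlhe41, Slc25a31 and P2rx7. By camera cholesterol synthesis (median -0.29, 23 genes, adjusted p 3.8e-06, estimated-correlation p 0.389), trophectoderm (median -0.16, 25 genes, adjusted p 0.00184, estimated-correlation p 0.389), cell cycle (median -0.12, 35 genes, adjusted p 0.0139, estimated-correlation p 0.384) and unfolded protein response genes (median -0.09, 22 genes, adjusted p 0.0491, estimated-correlation p 0.389) were lower, and ribosomal proteins (median 0.03, 85 genes, adjusted p 0.0312, estimated-correlation p 0.880) and oxidative phosphorylation (median 0.09, 78 genes, adjusted p 4.8e-06, estimated-correlation p 0.560) higher. At 4-cell the high dose did not differ from the low dose in any gene or list (edgeR 0, 202 at unadjusted p under 0.05, DESeq2 0).

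Whether the high-dose effect of miR-200c depends on stage was tested as morula effect minus 4-cell effect. The test passed the threshold in 43 of 11129 genes, among them Apoe, the transcription factor Tfcp2, the collagen chaperone Fkbp10 and Tdpoz3, and 4 of them passed the count filter at both stages. The effect was higher in morulae for 25 and lower for 18 (835 at unadjusted p under 0.05, DESeq2 16, 15 of them shared). Apoe was at 81.8 ± 32.5 against 51.5 ± 21.1 CPM in morulae (n = 19 and 20) and 28.6 ± 24.0 against 62.5 ± 55.0 CPM at 4-cell (n = 24 and 24), injected against control (log2 fold change 1.81, SE 0.43, adjusted p 0.0248). Tfcp2 was at 5.65 ± 3.40 against 15.9 ± 13.9 CPM in morulae (n = 19 and 20) and 109.5 ± 42.9 against 102 ± 40.2 CPM at 4-cell (n = 24 and 24) (log2 fold change -1.58, SE 0.35, adjusted p 0.0168). Fkbp10 (log2 fold change -3.40, SE 0.81, adjusted p 0.0248) was at 0.457 ± 0.742 against 4.84 ± 15.9 CPM in morulae. Without the highest embryo of each stage none of the 3 passed: Apoe gave 1.59 (adjusted p 0.0702), Tfcp2 -1.30 (adjusted p 0.0534) and Fkbp10 -1.49 (adjusted p 0.666). Tdpoz3 (log2 fold change -6.47, SE 1.44, adjusted p 0.0172) owes its call to high-dose 4-cell replicate 11, without which it gave -2.18 with adjusted p 0.682. Over the 9519 genes with enough counts at both stages, which leave out 39 of the 43, none passed (583 at unadjusted p under 0.05). There Apoe was at 1.81 (adjusted p 0.143) and Tfcp2 at -1.58 (adjusted p 0.105). Ribosomal proteins had a lower effect in morulae by camera (median -0.26, 85 genes, adjusted p 4.96e-21, estimated-correlation p 0.806).

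The effect of miR-200c in fertilized embryos minus that of the low dose in parthenotes gave 0 genes by edgeR at 4-cell (237 at unadjusted p under 0.05, DESeq2 0) and 0 at morula (406, smallest adjusted p 0.32, DESeq2 0). The dose in fertilized embryos is not stated, so embryo type and dose are not separated. By camera maternal transcripts had a higher effect in fertilized 4-cell embryos (median 0.58, 42 genes, adjusted p 4.97e-06, estimated-correlation p 0.977), ribosomal proteins a lower one there (median -0.06, 85 genes, adjusted p 0.000421, estimated-correlation p 0.977; median 0.03 with surrogate variables) and a higher one in morulae (median 0.06, 85 genes, adjusted p 1.62e-05, estimated-correlation p 0.826), and primitive endoderm genes a lower one in morulae (median -0.40, 11 genes, adjusted p 0.00959, estimated-correlation p 0.826).

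Over the 15 comparisons with controls, camera called 33 of 240 list tests, in 13 comparisons, and 0 with an estimated correlation. Lists of pluripotency and inner cell mass, interferon and RNA sensing, unfolded protein and integrated stress response, microRNA pathway, chromatin regulators, cell cycle and paternally expressed imprinted genes were called in none of them. Their smallest adjusted p, with the estimated-correlation p in parentheses, was 0.259 (0.587), 0.150 (0.539), 0.292 (0.584), 0.292 (0.660), 0.0610 (0.584), 0.136 (0.584) and 0.173 (0.665) in that order. Published miR-200 family targets were called higher in 1 comparison, mid-dose morulae, and lower in none.

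Genes with a 3' UTR seed site for the injected microRNA, the transcripts it would be predicted to repress, did not shift against genes without a site in any of the 15 comparisons (adjusted p at least 0.857). At the low dose of miR-200c in 2-cell parthenotes the seed site score differed from controls by -0.02 with SE 0.03 (n = 26 and 28), and at the mid dose by 0.07 with SE 0.04 (permutation p 0.0710). At 4-cell the 3 doses gave 0.02 with SE 0.04, 0.06 with SE 0.05 and 0.01 with SE 0.03, and in morulae 0.02 with SE 0.03, 0.02 with SE 0.02 and 0.00 with SE 0.03. Fertilized embryos gave 0.01 with SE 0.03 at 4-cell and 0.00 with SE 0.03 at morula. For miR-465c the score differed by 0.03 with SE 0.04 at 2-cell, -0.06 with SE 0.04 (permutation p 0.123) and -0.04 with SE 0.04 at 4-cell, low and high dose, and 0.02 with SE 0.03 and -0.01 with SE 0.03 at morula.

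**Figure D4:**
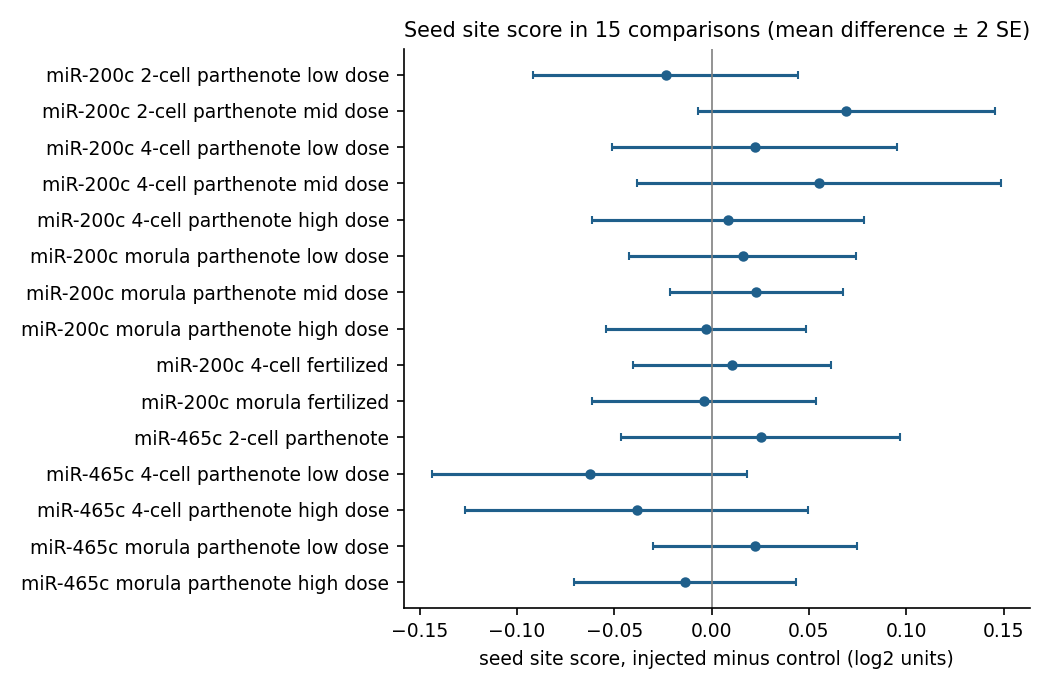
Seed site score, injected minus control, in log2 units for the 15 comparisons, with points for the mean difference and bars for 2 SE on each side. The differences run from -0.06 to 0.07, and every bar crosses 0.

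Fold changes of pairs of comparisons were correlated across genes, which are not independent replicates, to ask whether doses, stages, embryo types or microRNAs act alike. In none of 33 pairs did the covariance pass an adjusted p of 0.05 against random groupings of the embryos. The nearest pair was the mid and high dose of miR-200c in morulae, which share controls (r 0.733, against a mean of 0.485 in random groupings, adjusted p 0.0630). The low and mid dose at the 2-cell stage gave r 0.295 (random mean 0.461, adjusted p 0.388), and the high doses of miR-200c and miR-465c in morulae r -0.32 (adjusted p 0.0630).

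Fusing the editor to AGO2 raised editing of many transcripts over the editor alone. In 3' UTRs 313 of 2818 genes had more EPKM with AGO2 and 7 less, and in coding sequences 167 of 3323 had more and 3 less. After division of each embryo by its region total 158 were higher and 10 lower in 3' UTRs, and 81 higher and 25 lower in coding sequences. Fisher's exact test called 57 and 18, all higher. The largest rises in 3' UTRs were those of Fars2, a mitochondrial tRNA synthetase (chromosome 13, 36117643 to 36537595, log2 difference 6.24, SE 0.53, adjusted p 9.22e-18), at 53.2 ± 30.97 EPKM against 1.42 ± 2.96 (SD, n = 23 and 15), Noct (log2 difference 5.04, SE 0.32, adjusted p 4.68e-25), at 44.2 ± 22.8 EPKM against 1.43 ± 1.44, and the cell cycle regulator Cks2 (log2 difference 5.01, SE 0.50, adjusted p 3.15e-14), at 19.7 ± 12.8 EPKM against 1.21 ± 3.77. Golph3, a Golgi protein, followed in 3' UTRs (log2 difference 4.82, SE 0.33, adjusted p 4.87e-23) and led in coding sequences (log2 difference 6.47, SE 0.35, adjusted p 9.36e-31), at 71.6 ± 40.8 EPKM against 0.977 ± 1.18. The ubiquitin ligase Rnf14 completed the 3' UTR group (log2 difference 4.08, SE 0.28, adjusted p 4.87e-23). In coding sequences Rnf34 (log2 difference 4.52, SE 0.44, adjusted p 1.56e-14), Tcl1b3 (log2 difference 4.44, SE 0.35, adjusted p 2.96e-19), at 106 ± 50.7 EPKM against 8.17 ± 9.95, and Gid4 (log2 difference 3.94, SE 0.45, adjusted p 2.63e-11) rose, and Nxt2 was listed at 0 in all editor-alone embryos and at 5.67 ± 4.35 EPKM with AGO2 (adjusted p 7.52e-12).

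Some genes were lower with AGO2. Mybbp1a and Rxrb in 3' UTRs and Slc25a43 and Wdr20rt in coding sequences were listed at 0 in all AGO2 embryos, against 1.36 ± 2.00, 0.668 ± 0.995, 0.299 ± 0.634 and 0.138 ± 0.259 EPKM with the editor alone. The 3' UTRs of Ak6 (log2 difference -1.20, SE 0.38, adjusted p 0.0216), Pde4c (log2 difference -0.99, SE 0.30, adjusted p 0.0166) and Lrrc41 (log2 difference -0.66, SE 0.22, adjusted p 0.0356) and the coding sequence of Zfp386 (log2 difference -0.67, SE 0.20, adjusted p 0.0319) also fell. In introns 3 of 2445 genes passed: the predicted genes Gm11827 (log2 difference 4.52, SE 1.01, adjusted p 0.0175) and Gm1965 (log2 difference 1.33, SE 0.30, adjusted p 0.0175) were higher, and Gm9806 was listed at 0 with AGO2 and at 641 ± 1481 EPKM with the editor alone, above 0 in 4 of 15 embryos. The next intron genes were Zkscan1, Fars2 and Gclc, at log2 -2.01, 1.11 and -0.89 (adjusted p 0.0795 each).

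Summed EPKM per embryo was higher with AGO2 in 3' UTRs, 7691 ± 782 against 5151 ± 1008 (SD, n = 23 and 15, 1.51-fold, permutation p 1e-05, the smallest they can give), and in coding sequences, 4694 ± 624 against 3123 ± 168 (1.49-fold, permutation p 1e-05). Intron totals varied widely, 12252 ± 9555 against 9501 ± 8073 (permutation p 0.440). Adding miR-200c left the 3' UTR total at 7485 ± 910.2 (n = 27), the coding total at 4361 ± 516 and the intron total at 9338 ± 8937. With miR-465c they were 7997 ± 1541 (n = 28), 5388 ± 1339 and 12169 ± 9068. None of these 6 totals differed from AGO2 alone (adjusted p at least 0.0941).

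**Figure D5:**
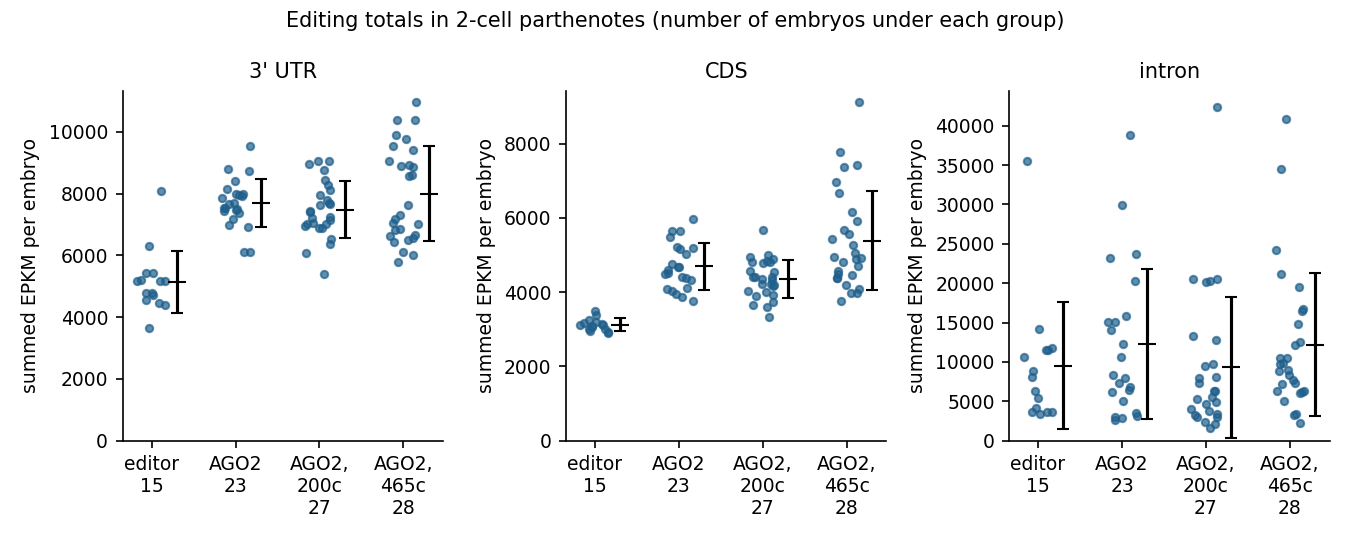
Summed EPKM per embryo in 3' UTRs, coding sequences and introns of 2-cell parthenotes, with 1 point per embryo. With AGO2 the 3' UTR totals average 7691 against 5151 for the editor alone, and the groups given a microRNA overlap AGO2 alone.

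Which transcripts gain editing when a microRNA is added asks for its direct targets. With miR-465c 1 of the 3' UTRs tested changed: Rtbdn (chromosome 8, 84946991 to 84956606) fell, from 2.24 ± 1.97 to 0.421 ± 0.941 EPKM (log2 difference -1.84, SE 0.40, adjusted p 0.0438), above 0 in 5 of 28 against 16 of 23 embryos. The call is lost with either other pseudocount, without the filter, by Fisher's exact test (smallest adjusted p 0.664) and after division by the region total (0.124). Next were Arhgef3 (log2 difference -0.79, SE 0.21, adjusted p 0.312), Tbc1d9 (log2 difference -0.69, SE 0.19, adjusted p 0.312) and Rps27l (log2 difference 1.95, SE 0.55, adjusted p 0.312). The miR-200c comparison shares these AGO2 controls, so a fall in both is not replication. Its smallest p in 3' UTRs were those of Rtbdn (log2 difference -1.74, SE 0.41), Smim20 (-1.76, SE 0.42) and Mapkap1 (-1.24, SE 0.30, adjusted p 0.0576 each). limma called 0 of 2898 3' UTRs there (214 at unadjusted p under 0.05, Fisher's exact test 0). In coding sequences limma called 0 of 3373 genes with miR-200c (257 at unadjusted p under 0.05, Fisher 0) and 0 of 3425 with miR-465c (233, Fisher 0), and in introns 0 of 2407 (196, Fisher 0) and 0 of 2436 (177, Fisher 0).

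The smallest p values in coding sequences were those of Fam199x (-1.49), Tmem106a (1.16) and Lcmt1 (-0.71, log2, adjusted p 0.432 each) with miR-200c, and of Skap1 (0.90), Mbl2 (1.24) and the proteasome subunit Psmb6 (1.41, adjusted p 0.427 each) with miR-465c. In introns they were Tmem175 and Mgrn1, listed at 0 with miR-200c, and Nip7 (log2 difference 2.42, SE 0.71, adjusted p 0.422), and with miR-465c Slc1a5 (-1.999), Psmb6 (3.59) and Slc35f3 (-0.73, adjusted p 0.152 each). The share of 3' UTR EPKM in genes with a seed site was 11.02% ± 4.65 with miR-200c against 11.5% ± 4.87 with AGO2 alone (SD, n = 27 and 23, permutation p 0.722). With miR-465c it was 4.20% ± 0.462 against 3.94% ± 0.445 (n = 28 and 23, permutation p 0.0475, adjusted p 0.0949).

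The 50 genes with the smallest p for more 3' UTR editing with each microRNA were then followed in the injected embryos, where targets would be predicted to fall. The list was called in none of the 15 comparisons. It came nearest at the mid dose of miR-200c in 2-cell parthenotes (median log2 fold change -0.21, adjusted p 0.271), and at the low dose there the median was 0.01 (adjusted p 0.960). With 200 genes in place of 50 the list was called lower at that mid dose (adjusted p 0.00221). The list of the other microRNA (0.0295) and that of genes edited more with AGO2 (0.000108) were called higher there. With an estimated correlation none of these holds (adjusted p 0.386, 0.791 and 0.949). No gene of either list had passed the threshold for higher editing, so the lists hold the nearest genes rather than identified targets.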

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

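The tests of counts per stage, that on genes with enough counts at both stages, that with bands of embryo numbers and those on single embryos were chosen after the result was seen; the interaction itself was set before. A direct test of whether the high dose of miR-200c acts differently in morulae and in 4-cell parthenotes gave 43 genes past the threshold, a difference between groups, 25 higher and 18 lower in morulae.

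A gene expressed at a single stage can give such a difference through a few embryos at the other. Of the 43 genes, 8 (18.6%) had enough counts at 4-cell to be tested there alone and 38 at morula, and a called gene had counts in a median of 4 of 48 4-cell embryos, against 47 for the other genes tested. These values go with counts in few 4-cell embryos, except for the 8 (median 48 of 48). Of the 8, 4 passed the filter at morula, where sparse counts were untested. A fit over the 9519 genes testable at both stages (583 at unadjusted p under 0.05) called 0, but decides nothing on the 39 left out. Chance cannot be excluded for the count: 14 of 30 splits of the same embryos gave as many genes, with a highest other count of 71, a sign of structure among the embryos, and 26 of 30 gave at least 1 list as the real split did (highest other 6). At unadjusted p under 0.05, by contrast, 835 genes were reached by the real split alone of the 30 (highest other 770). The count of 43 was 16 by DESeq2, 12 with bands of embryo numbers and 52 without high-dose 4-cell replicate 11. A difference between the stages in how embryos respond to miR-200c, which the design allows, was not tested further and stays open.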

How the results depend on the processing

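Limits of the design bear on every result above. With about 20 embryos per group and large differences between single embryos, tests on simulated counts recovered from 14.9% to 71.6% of 2-fold changes, so an absence of called genes leaves 2-fold and smaller changes open. Genes below about 1 CPM are limited by counting and lean on the low count filter. Results that no test made, such as sperm levels, have no call to change. With 1 sperm sample left out, the mean of miR-200c-3p ran from 394 to 569.8 RPM, miR-465c-3p from 414 to 665 RPM and miR-10b-5p from 163465 to 187840.3 RPM. Of gene counts under other settings, 81 stayed within 1.5 times, 39 larger and 15 smaller; of list counts 96, 11 and 74; of EPKM gene counts 40 stayed and 14 smaller. Single lists kept call and direction in 195 cases, lost the call in 169 and turned in 12, and named genes kept theirs in 427 cases, gained a call in 70, lost it in 45 and turned in 31. Values that round to 0.00 were taken as without direction. The cause of a change was not tested except where stated. Counts that moved by over 1.5 times and values that turned are given below by setting.

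Among the settings fixed before the data were examined, dropping the low count filter raised every gene count. Most of the genes called then are ones the filter removes, but from 2 to 261 per contrast (261 between mid and low dose at 2-cell) are ones it keeps. Against controls it gave 1206 and 1410 genes at the low and mid dose of miR-200c at 2-cell, 1350, 1433 and 1522 at the low, mid and high dose at 4-cell, and 338, 189 and 278 in morulae. Fertilized embryos gave 1029 at 4-cell and 277 at morula. For miR-465c it gave 1548 at 2-cell, 1601 and 1364 at 4-cell and 347 and 539 in morulae. Between doses it gave 1740 at 2-cell, 1291 at 4-cell and 252 at morula for miR-200c, and 1403 and 493 at 4-cell and morula for miR-465c. The interactions gave 746 for stage and 714 and 249 for embryo type at 4-cell and morula.

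DESeq2 called 478 genes at the mid dose of miR-200c at 2-cell and 345 between mid and low dose, 10 and 1 at the mid and high dose at 4-cell, 0 between high and low dose there, 1 and 3 at the mid and high dose in morulae, 27 for high miR-465c in morulae and 3 between its doses, and 16 for stage. It turned Zscan4f to -0.68, Zscan4d to -0.15 and Zscan4c to -2.11 at the high dose, Zscan4f to -0.07, Zscan4d to -0.09 and BB287469 to -0.57 between doses, and Dicer1 to 0.02 at the mid dose at 4-cell. Without mid-dose replicate 26 of the 2-cell stage (a setting added later) DESeq2 called 135 genes against controls and 112 against the low dose. RLE normalization gave 1 gene and 4 lists at the high dose at 4-cell, 3 genes for high miR-465c in morulae, and turned Dicer1 to 0.02 at the mid dose at 4-cell. Leaving out shallow embryos, for lists also a setting added later, gave 0 lists for miR-465c at 2-cell and 0 for its low dose at 4-cell, where oxidative phosphorylation turned to -0.01.

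From 1 to 7 embryos per table correlated best with their own number (median same-number r at most 0.0414). Within groups, median r was higher within number bands than between them in every table. With the number as a block, gene counts were 524 at the mid dose of miR-200c at 2-cell and 225 between mid and low dose, 1 and 0 at the mid and high dose at 4-cell and 0 between high and low, 1 at the high dose in morulae and 1 between high and low, 4 in fertilized morulae, 1 for low miR-465c at 4-cell, 1 between its doses there and 0 in morulae. The interactions gave 2 for stage and 1 for embryo type in morulae. Lists called were 1 at the low dose at 2-cell, 2 at the low dose and 0 between high and low dose in morulae, 1 in fertilized 4-cell embryos and 3 for low miR-465c at 4-cell. Oxidative phosphorylation turned to -0.04 at the low dose in morulae, and ribosomal proteins to -0.01 between miR-465c doses. EPKM genes were 0 in 3' UTRs with miR-465c and 0 in introns with AGO2. Genes that turned were Zeb1 (-0.17) and Ago2 (-0.03) at the low dose at 2-cell, Zeb1 (1.82) and Dicer1 (0.01) at the mid dose at 4-cell, Dicer1 (0.02) in fertilized 4-cell embryos, Zscan4f (-0.39) and Zscan4c (-1.69) at the high dose, and Zscan4f (-0.20) and BB287469 (-0.22) between doses.

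With surrogate variables gene counts were 1 and 0 at the mid and high dose of miR-200c at 4-cell, 0 between high and low dose, and 0 between miR-465c doses in morulae. Lists called were 1 at the low dose at 2-cell, 2, 1 and 0 at the low, mid and high dose at 4-cell, 1 and 2 at the low and high dose in morulae, 1 in fertilized 4-cell embryos, 2 and 3 for low and high miR-465c at 4-cell, 2 for stage, and 0 and 0 for embryo type. Medians turned to -0.01 for oxidative phosphorylation at low miR-200c in morulae and 0.04 at low miR-465c, 0.07 for trophectoderm and 0.03 for cholesterol synthesis at high miR-465c in morulae, -0.07 for maternal transcripts between doses at 2-cell, and 0.03 for ribosomal proteins by embryo type at 4-cell. Surrogate variables are built from the data and can absorb a shift shared by many genes. Dicer1 turned to 0.01, 0.04 and 0.15 at the 3 doses at 4-cell and 0.04 in fertilized 4-cell embryos.

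With a correlation estimated from the data, camera called 0 lists in all, where the preset had called 50 over 23 contrasts, so the count fell to 0 in each of the 20 contrasts that had a call. Seed site scores stayed without a call. They turned with 8mer sites only to -0.02 at high miR-200c at 4-cell and -0.02 at low miR-465c in morulae, and with matching on 3' UTR length and expression to -0.01 at mid miR-200c in morulae, -0.01 and 0.01 for miR-465c at 2-cell and at the high dose at 4-cell, and -0.01 at its low dose in morulae. The Rtbdn call with miR-465c was lost with either other pseudocount, without a filter (0 genes), by Fisher's exact test (0) and after division by the region total (0). For AGO2 over the editor alone, Fisher's exact test gave 57 genes in 3' UTRs, 18 in coding sequences and 0 in introns, division by the total 168, 106 and 1, and no filter 0 in introns. Counting genes above 0 instead of summing EPKM turned the miR-465c difference to -0.07 in 3' UTRs, -0.10 in coding sequences and -0.08 in introns (log2). The list of genes edited with the microRNA was called in 1 comparison with 200 genes instead of 50, lower at the mid dose of miR-200c at 2-cell.

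The remaining settings were added after the data were seen. With bands of 8 embryo numbers as a factor, gene counts were 239 at the mid dose of miR-200c at 2-cell, 1 and 0 at the mid and high dose at 4-cell, 0 between high and low dose, 2 for high miR-465c in morulae and 12 for stage. Lists called were 1 at the low dose at 2-cell, 2 at the low dose and 0 between doses in morulae, and 2 and 1 for low miR-465c at 4-cell and morula. Ribosomal proteins turned to -0.06 at the low dose at 2-cell, oxidative phosphorylation to -0.05 at the low dose in morulae, and Dicer1 to 0.01 at the mid dose at 4-cell. Without high-dose replicate 11, 0 genes differed between high and low dose at 4-cell and 4 lists were called against controls, none of them with an estimated correlation, zygotic activation genes (median -0.61) and chromatin regulators (-0.07) newly and lower, with Zscan4f at -1.23, Zscan4d at -0.07 and Zscan4c at -2.46 against controls and Zscan4f at -0.69, Zscan4d at -0.06 and BB287469 at -0.53 against the low dose. Without the embryo with its highest value, Zeb1 turned to 0.17 and 0.36 at the low and mid dose at 4-cell, and Socs3, Gm10697, Bhlhe41 and the stage effects of Apoe, Tfcp2 and Fkbp10 lost their call. Among genes tested at both stages, which leave out 39 of the 43, 0 differed in effect. With Y-linked counts as a covariate 1 list was called in fertilized 4-cell embryos and Dicer1 turned to 0.03.

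Permutation of list scores called 2 lists at the mid dose of miR-200c at 2-cell, and 0 in each of the other 15 contrasts whose count changed. Within number bands it called 2 lists between mid and low dose at 2-cell and 0 in the other 15, and oxidative phosphorylation turned to -0.03 at the low dose in morulae. Without shallow embryos it called 2 lists at the mid dose at 2-cell, 2 between mid and low dose, and 0, 0 and 0 at low miR-200c at 2-cell and for miR-465c at 2-cell and at its low dose at 4-cell. With the site of the other microRNA, seed scores turned to -0.03 and -0.01 at the low and high dose of miR-200c at 4-cell and 0.05 at high miR-465c in morulae, and the seed site share with miR-465c to -1.0 points. At the mid dose of miR-200c at 2-cell the list of the other microRNA was called (1 comparison, higher), as was that of genes edited more with AGO2 (1 comparison, higher). Neither these calls nor that with 200 genes hold with an estimated correlation (adjusted p at least 0.386).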

Other observations

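The tests of this part that were chosen after the results were seen are those of embryos with and without Y-linked counts, of list scores, of bands of embryo numbers and of other splits of the embryos; division of editing by its total was set before, and its use as a test here after. Among fertilized embryos, Y-linked counts separated 20 embryos with from 22 without them at 4-cell, and 21 from 25 at morula, and no parthenote had any. At 4-cell 12 of 288 X-linked genes tested were called lower in embryos with a Y chromosome, among them the kinase Cdk16, at 200 ± 49.6 against 327 ± 75.6 CPM (SD, n = 20 and 22, log2 -0.73, adjusted p 0.000146). The median of all 288 was -0.37, and that of autosomal genes 0.02. In morulae Xist, the RNA that silences an X chromosome, was at 4.90 ± 13.6 against 99.4 ± 72.4 CPM (log2 -4.77, adjusted p 5.53e-08), and the median of X-linked genes was -0.51. At 4-cell 13 genes differed in all, and in morulae 86, of which 67 were X-linked and lower, 2 Y-linked and 16 autosomal, and Uba1y, absent without a Y, has no chromosome in the annotation. Splits within the groups exclude chance, with 1 of 30 as large at each stage, the real one, and highest other counts of 2 and 0.

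Some paternally expressed imprinted genes stood higher in fertilized than in parthenogenetic morulae, which lack a paternal genome. Among controls, the amino acid transporter Slc38a4 was at 36.5 ± 29.5 CPM in fertilized morulae (SD, n = 23) and 0.453 ± 1.58 CPM in parthenotes (n = 20). Impact was at 27.2 ± 17.8 and 2.60 ± 2.42 CPM. Of the 25 genes of the list, 15 had a mean of at least 1 CPM in either group, 10 of them at least 2-fold higher in fertilized morulae and 5 less than 2-fold apart, such as Sgce (8.80 ± 6.23 and 5.65 ± 5.69 CPM). The genes named were chosen after their values were seen, and the experiments were separate, so no test was made.

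Lower ribosomal protein transcripts at the mid dose of miR-200c in 2-cell parthenotes could have technical sources. The embryo with the lowest score, mid-dose replicate 26 at -2.05 against a group median of 0.92, is not the whole source, since without it the difference was -0.63 with permutation p 0.00797. Depth is argued against too, as 98.3% of the difference was left after adjustment for total counts. So are effects of number bands (permutation p 0.00024 within them), but bands need not be days. A few genes taking most of the counts stays undecided. Adjusted for the share of the 10 most abundant genes 22.9% was left, but that share itself differed by dose. Less advanced embryos also stay open, since the ribosomal protein score was lower where the maternal score was higher, with r -0.6944 across 28 control embryos (permutation p 5e-05, adjusted p 0.0002, rho -0.74 with p 2e-05, r -0.64 without the 2 farthest embryos), though with r -0.17 in 22 controls of the miR-465c experiment (permutation p 0.453, adjusted p 0.453, rho -0.21 with p 0.355, r -0.04 without the 2 farthest). Scores of zygotic activation genes, the other sign of progress, did not rise with ribosomal protein scores beyond chance in either set (r 0.19 with permutation p 0.344, and -0.24 with p 0.273), which leaves this undecided.

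More editing with AGO2 than with the editor alone was weighed against 3 sources. A higher total as the whole source is argued against, since after division by the embryo's total 158 of all 2818 genes tested were still called higher in 3' UTRs and 10 lower. The other 155 of the 313 lost their call, with a median difference of 1.17 before and 0.86 after division. Longer 3' UTRs are argued against by a ratio of median lengths of 1.0391 (1277 against 1229 bases, Wilcoxon p 0.0928). More sites of the microRNA families listed beforehand stay open: a missed threshold, set beforehand as the sign against them, does not show that sites are not more frequent, and miR-17-5p sites were in 20.9% of higher genes against 15.01% of the others (log2 odds ratio 0.50, SE 0.23, unadjusted p 0.0312, adjusted p 0.1247). Sites of miR-10-5p were fewer among the higher genes (log2 odds ratio -1.02, adjusted p 0.00822). Binding by AGO2, which the design compares, stays open as a hypothesis. Chance is excluded for 3' UTRs (real value 320, highest other 42) and coding sequences (170, highest other 17), with 1 of 100 splits as large in each, and not for introns (3, highest other 5, 7 of 100).

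Other groupings of the same embryos show how far counts of genes can come from chance. At the mid dose of miR-200c at 4-cell 4 of 30 splits gave as many genes as the real 2 (highest other 2), at the high dose 24 of 30 (real value 2, highest other 14), and between high and low dose there 30 of 30 (real value 4, highest other 14), so chance cannot be excluded for any of these. For Bhlhe41 between miR-465c doses in morulae 3 of 30 gave as many (real value 1, highest other 2). In the other contrasts the real 0 tests nothing, as any split reaches it. Some of those splits called many genes, up to 125 with high miR-465c in morulae, 98 with miR-465c at 2-cell and 61 with low miR-200c in morulae. The reason, such as a structure of the samples other than treatment, was not tested. At unadjusted p under 0.05 the mid dose at 2-cell had 1857 genes against a highest other count of 496, mid against low there 1715 against 1299 and the high dose in morulae 715 against 674, each reached by the real split alone, and the low dose at 2-cell 136 against 1275. With EPKM the 4 counts of 0 in coding sequences and introns and that of miR-200c in 3' UTRs were also reached by any split (highest other 3), and the 1 gene of miR-465c in 3' UTRs, Rtbdn, by 18 of 100 (highest other 2).

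For the number of lists that camera called, chance cannot be excluded in any contrast with a call. The nearest were mid miR-200c in morulae (real value 6, highest other 6) and high against low miR-465c in morulae (real value 6, highest other 6), each with 2 of 30 splits as large. At 2-cell 24 of 30 splits gave as many lists as the low dose of miR-200c (2, highest other 5), 10 as the mid dose (4, highest other 5), 8 as mid against low (4, highest other 6) and 27 as miR-465c (1, highest other 4). At 4-cell they were 20 for the low (1, highest other 5), 25 for the mid (2, highest other 6) and 15 for the high dose of miR-200c (2, highest other 5), 22 for high against low (1, highest other 4) and 27 for low miR-465c (1, highest other 4). In morulae they were 12 for the low (4, highest other 6) and 10 for the high dose of miR-200c (4, highest other 6), 30 for high against low (1, highest other 8), 25 in fertilized morulae (1, highest other 6), and 21 and 16 for low and high miR-465c (2 and 3, highest others 5 and 7). For embryo type they were 20 at 4-cell (2, highest other 6) and 27 at morula (2, highest other 7). The 3 contrasts without a called list test nothing.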
